A study of Homo sapiens with 8 samples.

How the data were processed

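RNA was sequenced from 8 libraries of SNU475 cells, an established human hepatocellular carcinoma line. Of these, 4 libraries came from cells given a non-targeting control siRNA (siNC) and 4 from cells given an siRNA against ZFP36L1 (siZFP36L1). The labels number the libraries 1, 2, 4 and 5 in each group, and the design text describes independent experiments, so p-values measure the spread between experiments in 1 cell line.

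The authors deposited FPKM values (fragments scaled by exon length and by library) in 1 table of 58735 Ensembl genes. Per the submitters' processing notes, reads were handled with fastp, STAR 2.6.1d, featureCounts 1.5 and DESeq2 on the GRCh38 build; the order, the settings and the strand rule are not given in the sources used here. All 58735 identifiers were found in GENCODE release 29, which supplied gene type, coordinates and exon length, and 41937 had a gene symbol.

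Whole reads could be worked back from the deposited FPKM. Each FPKM multiplied by the gene's summed exon length and by 1 divisor per library came within 0.01 of a whole number for 100% of values in every library. Totals worked back in this way ran from 12.9 to 26.7 M reads per library. The divisor was not the read total: it equalled the library's median-of-ratios size factor times the geometric mean of the 8 totals (ratio 1.0 in each library), so the deposited FPKM already carried a between-library scaling. Depth and group went partly together, with 21.4 ± 3.72 M reads (SD, n = 4) for siNC and 17.4 ± 4.02 M (SD, n = 4) for siZFP36L1.

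FPKM is not a count, so the test was linear and on the log scale. The values were taken as log2(FPKM + 0.5), which understates the change of low genes, and genes with a mean FPKM of at least 0.5 over the 8 libraries were kept, 14789 in all. limma 3.58.1 in R 4.3.3 was fitted with group as the only term and eBayes with a trend, two-sided, with Benjamini-Hochberg adjustment over the 14789 genes and a threshold of 0.05. An adjusted p of a single gene named without a method is from this limma fit, one called blocked or given with the block is from the limma fit with the experiment number as a block, and one of a gene list is from camera unless fry is named. The exact permutation test of single genes went through the 70 assignments of 8 libraries to 2 groups of 4, two-sided, and cannot give a p below 0.0286.

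The 17 gene lists were fixed before the data were examined and tested with camera (inter-gene correlation 0.01) with Benjamini-Hochberg adjustment over the lists. ZFP36L1 was left out of the test of its own list. camera compares a list with the other genes. fry tests whether a list's genes move, on balance, one way, and does not compare the list with other genes or lists. DDX58 and RIGI name 1 gene and were counted once.

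The numbers shared by the groups were taken to pair the libraries, because the labels give 1 control and 1 knockdown library the same individual number and the design text describes separate experiments. As a check, deviations from the group means correlated at 0.26 within number 1, 0.03 within number 2, 0.52 within number 4 and 0.54 within number 5, across genes. Knockdown libraries 4 and 5 correlated best with the control of their own number. Knockdown 1 correlated more with control 2 (0.32) and knockdown 2 more with control 1 (0.07), while control 1 correlated best with knockdown 1. These correlations therefore do not settle the pairing for numbers 1 and 2, which follows the labels. The fit with the number as a block was an alternative, and its value stands beside each result whose call it changes.

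Genes were named by a rule fixed before the data were examined. It took ZFP36L1 and ZEB2. It then took up to 10 genes per direction with the largest change among genes with a symbol, a mean FPKM of at least 1, an adjusted p under 0.05 and 1 direction in all 4 pairs. From each list it took up to 3 members with the lowest p where a member passed, and otherwise 2. ZFP36, ZFP36L2, CDH1, CDH2, VIM, SNAI1, SNAI2, ZEB1 and TWIST1 were given whatever their values. A gene that the rule took is not reported here. FP671120.1 has no symbol and lies outside the rule; it was named after its values were seen, as were ETS1, CLDN1, ELF3, PMEPA1, SMURF2 and SLC7A11, which passed over their list alone with the block.

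Other settings fixed before the data were examined were pseudocounts of 0.1 and 1, no filter, a mean FPKM of at least 1, a second scaling by median-of-ratios factors, quantile normalization, the replicate block, limma arrayWeights, eBayes without trend, each library left out in turn, camera with an estimated correlation, fry, and a minimum absolute log2 fold change of 1. Added after the data were seen were limma voom on the worked-back reads, the fit without knockdown libraries 2 and 4, the block with arrayWeights, and the block with fry.

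The limma step was tested on simulated data of the siZFP36L1 against siNC comparison with 14789 genes, 200 of them changed, in 5 draws. It recovered 15.6% of genes changed 2-fold and 57.0% of genes changed 4-fold, and 7.40% of its calls were unchanged genes. For 3' UTR sequences, the longest annotated 3' UTR of each gene was searched for heptamers in 11607 of the 11663 protein-coding genes tested (99.5%), ZFP36L1 itself excluded. Heptamers found in at least 50 genes and missing from at least 50 were compared after adjustment for 3' UTR length, GC content and mean FPKM, 16193 in all. Python 3.11.15, numpy, pandas, scipy and matplotlib were used for these steps and the figures.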

Results

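The data are RNA-seq profiles of SNU475, a human hepatocellular carcinoma cell line, 4 libraries after a non-targeting siRNA (siNC) and 4 after an siRNA against ZFP36L1 (siZFP36L1). ZFP36L1 encodes an RNA-binding protein of the tristetraprolin family, which binds AU-rich elements in 3' UTRs and promotes decay of the mRNA. The reads worked back from FPKM ran from 18.5 to 26.7 M in the siNC libraries and from 12.9 to 22.3 M in the siZFP36L1 libraries. Genes above 0 numbered 26033 ± 1478 (SD, n = 4) in siNC and 23346 ± 2843 (SD, n = 4) in siZFP36L1. Knockdown library 2 had 19897 such genes and knockdown library 4 had 22626. These 2 libraries also held few genes with a single read, 581 and 1245, against 2270 to 3800 in the other 6. The series title sets the question of whether silencing ZFP36L1 promotes epithelial-mesenchymal transition (EMT) in liver cancer cells through the transcription factor ZEB2.

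**Figure D1:**
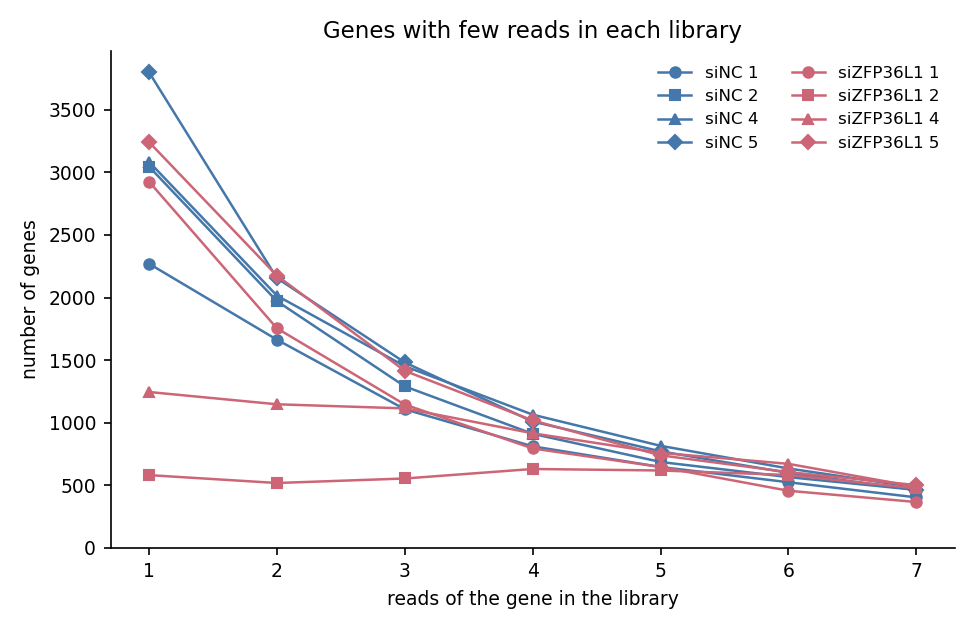
Number of genes (vertical axis) with exactly 1 to 7 reads (horizontal axis) in each library, siNC in blue and siZFP36L1 in red, with 1 marker shape per experiment number. Knockdown libraries 2 and 4 start at 581 and 1245 genes with 1 read, below the other 6 libraries.

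After ZFP36L1 siRNA its own mRNA fell, and MET, a growth factor receptor, and SRPRA, part of the machinery that brings secreted proteins to the endoplasmic reticulum, rose. TRIM26, RAB14 and PUDP fell. None of these calls was kept with the experiment number as a block (adjusted p 0.0529 to 0.0863 over all called genes). The standard errors of the called genes were smaller with the block, which also leaves fewer degrees of freedom. The EMT regulator ZEB2 was higher in every knockdown library, though not past the threshold over all genes. Epithelial markers, among them CLDN3 and JUP, fell as a group in the list test with a preset correlation. The call was lost with an estimated correlation (camera adjusted p = 0.0999), though the estimate, -0.00171, lay below the preset 0.01. Most other splits of the libraries called as many lists of any kind, a count that does not show whether epithelial markers were among them. Mesenchymal markers and the known targets of the ZFP36 family did not move as groups.

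ZFP36L1 (ENSG00000185650, GRCh38 chromosome 14, 68787660 to 68796253, minus strand) fell from 64.9 ± 25.2 FPKM (SD, n = 4) in siNC to 7.22 ± 1.08 FPKM (SD, n = 4) in siZFP36L1, 11.1% of the control mean. Every knockdown library, at 5.76 to 8.26 FPKM, lay below every control, at 44.8 to 101 FPKM, on 404 to 839 and 5908 to 9901 reads. The log2 difference was -3.02 (SE 0.26, limma adjusted p = 0.00388, or 0.0531 with the experiment number as a block). MET, the receptor tyrosine kinase for hepatocyte growth factor (chromosome 7, 116672390 to 116798386), rose from 9.5 ± 1.12 to 56.4 ± 17.5 FPKM (SD, n = 4 each), a log2 difference of 2.46 (SE 0.23, limma adjusted p = 0.00660, blocked 0.0531). SRPRA, a subunit of the signal recognition particle receptor (chromosome 11, 126262919 to 126269144), rose from 26.4 ± 4.02 to 67.8 ± 3.95 FPKM (limma adjusted p = 0.0395, blocked 0.0863).

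Besides ZFP36L1, 3 genes with a symbol fell. TRIM26, which encodes an E3 ubiquitin ligase (chromosome 6, 30184455 to 30213427), fell from 20.7 ± 4.12 to 4.96 ± 1.48 FPKM (limma adjusted p = 0.0251, blocked 0.0699). RAB14, a small GTPase of endosomal transport (chromosome 9, 121178137 to 121223014), fell from 33.6 ± 4.66 to 10.8 ± 1.41 FPKM (limma adjusted p = 0.0170, blocked 0.0699). PUDP, a pseudouridine phosphatase (chromosome X, 7048920 to 7148190), fell from 11 ± 0.94 to 3.76 ± 0.67 FPKM (limma adjusted p = 0.0238, blocked 0.0702). The 3' UTRs of TRIM26, RAB14 and PUDP hold the heptamer ACAUCUU 3, 2 and 1 times, and the 3' UTRs of ZFP36L1 and of MET, which rose, hold it once. FP671120.1, a long non-coding RNA annotated on chromosome 21 (8197620 to 8227646) and singled out after its values were seen, fell from 7.22 ± 1.75 FPKM to 0 in 3 knockdown libraries and 0.447 FPKM in knockdown library 5 (limma adjusted p = 0.00219, blocked 0.0529). This locus lies among repeated ribosomal DNA, where reads can fit several copies, so its level is uncertain.

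In all, 7 of 14789 genes changed at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment, 2 higher and 5 lower, each in 4 of 4 pairs. At an unadjusted p under 0.05 there were 1556 genes, 765 higher and 791 lower, against 739 by chance. The groups did not overlap for 946 genes (6.4%), where chance gives 2.86%. Both chance values take the libraries as exchangeable. Other splits of them gave 51 to 2918 genes at an unadjusted p under 0.05, and 3 exceeded the real 1556. The excess over 739 alone therefore does not show an effect of the knockdown. With the experiment number as a block, limma called 0 genes (lowest adjusted p = 0.0529), with 2374 at an unadjusted p under 0.05. So none of the 7 calls was kept with the block. The standard errors of the 7 were nonetheless smaller with it, for example 0.194 against 0.233 for MET. The block also leaves fewer degrees of freedom, so the lost calls do not by themselves show disagreement between experiments. Without knockdown libraries 2 and 4, limma called 0 genes (758 at an unadjusted p under 0.05), and leaving out 1 library gave 2 calls (control 1 or 5), 3 (control 4 or knockdown 4), 4 (control 2), 5 (knockdown 2 or 5) or 20 (knockdown 1). ZFP36L1 and FP671120.1 passed with any 1 library left out, and MET with any but control 1 (adjusted p = 0.0511) or control 5 (0.0543). Of the same 8 fits, RAB14 and PUDP passed only without knockdown 1 or 2, and SRPRA and TRIM26 only without knockdown 1. Over all alternatives the adjusted p reached 0.136 for MET, 0.255 for SRPRA, 0.240 for TRIM26, 0.151 for RAB14 and 0.172 for PUDP and ZFP36L1. limma voom on the worked-back reads called 12 genes.

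**Figure D2:**
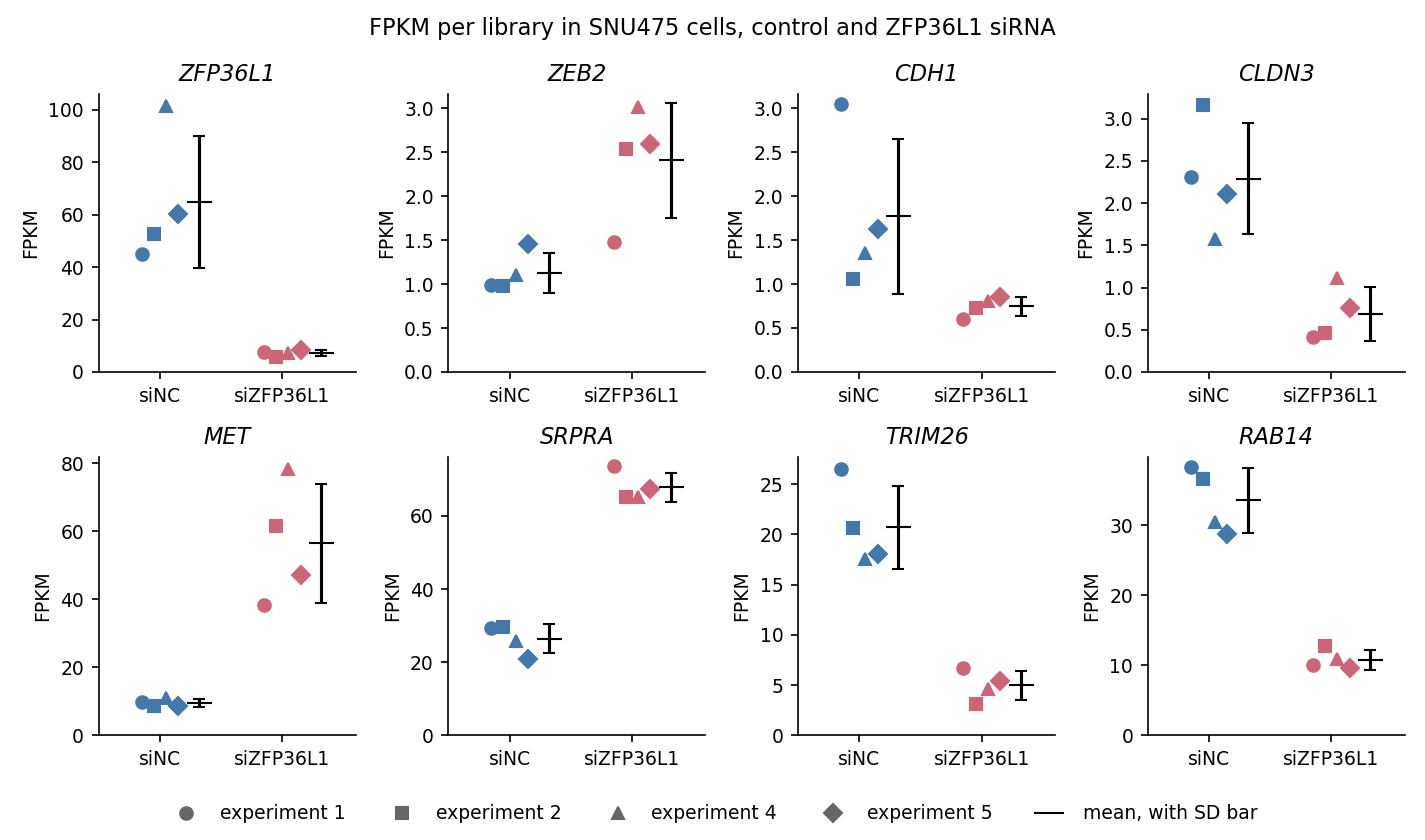
FPKM (vertical axes, linear from 0) of 8 genes in each siNC (blue) and siZFP36L1 (red) library, with 1 marker shape per experiment number; bars are mean and SD, n = 4. ZFP36L1 lies at 5.76 to 8.26 FPKM in the knockdown libraries and 44.8 to 101 FPKM in the controls, and MET at 38.4 to 78.4 and 8.56 to 10.9 FPKM.

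ZEB2, a transcriptional repressor of epithelial genes (ENSG00000169554, chromosome 2, 144364364 to 144524583, minus strand), averaged 1.13 ± 0.23 FPKM in siNC and 2.41 ± 0.65 FPKM in siZFP36L1 (SD, n = 4 each). All 4 knockdown libraries, at 1.48 to 3.01 FPKM, lay above the 4 controls, at 0.976 to 1.46 FPKM, on 521 to 1282 reads per library. The log2 difference of 0.81 (SE 0.23) had an exact permutation p of 0.0286, the smallest possible here. It did not pass over all genes (limma adjusted p = 0.297), and adjusted over the list alone its p was 0.0785, or 0.0343 in the blocked fit. None of the 14 measured EMT transcription factors passed over all genes or adjusted over the list alone, with 2 higher and 0 lower at an unadjusted p under 0.05. In the blocked fit 2 passed over the list alone, ZEB2 and ETS1. The list's median log2 difference was 0.11 (camera adjusted p = 0.315). ZEB1 differed by 0.69 (limma adjusted p = 0.432, higher in 3 of 4 pairs), or by 0.26 without knockdown libraries 2 and 4. SNAI1 differed by -0.73, SNAI2 by 0.55 and TWIST1 by 0.01, the last of which turned negative when the values were rescaled (-0.000801) or quantile normalized (-0.0179). With 1 library left out, SNAI1 ranged from -1.19 (without control 5) to -0.49 (without control 4) and SNAI2 from 0.09 (without control 5) to 1.03 (without control 2).

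Epithelial markers, the genes of cell junctions and of epithelial identity, fell as a group. Their median log2 difference was -0.48, 18 of 23 measured members were lower, and all 4 knockdown libraries lay below the control mean. camera gave an adjusted p of 0.00272, and 0.00435 in the blocked fit. The call was lost with an estimated correlation (adjusted p = 0.0999, blocked 0.624) and without knockdown library 1 (median -0.59, camera adjusted p = 0.0946). Without the block the estimated correlation was -0.00171, below the preset 0.01. A correlation between members above the preset value therefore does not account for that loss without the block. fry gave an adjusted p of 0.0116, or 0.213 with the block, and the list's mean level had an exact permutation p of 0.0286 (adjusted p = 0.243 over the 17 lists). Of the 35 splits of the libraries, 33 called at least 2 lists by camera, the number of the real split. That count covers any of the 17 lists and does not show how often epithelial markers were called. No member passed over all genes; 2 passed lower and 0 higher adjusted over the list alone. These were CLDN3, a tight junction claudin, at 2.29 ± 0.66 FPKM in siNC and 0.687 ± 0.32 FPKM in siZFP36L1, and JUP, the junction protein plakoglobin, at 26.0 ± 4.09 and 14.3 ± 4.00 FPKM (SD, n = 4). With the block, 3 members passed lower over the list alone, CLDN3, JUP and ELF3, and 1 higher, CLDN1. CDH1, which encodes E-cadherin, averaged 1.77 ± 0.88 and 0.746 ± 0.11 FPKM, a log2 difference of -0.80 in 4 of 4 pairs (limma adjusted p = 0.377, 0.0772 over the list alone).

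Mesenchymal markers did not move as a group. Of 38 measured members 23 were higher and 15 lower, the median was 0.17 (camera adjusted p = 0.345), and none passed over all genes or adjusted over the list alone. VIM, an intermediate filament gene, differed by 0.49 (limma adjusted p = 0.545, 4 of 4 pairs) and CDH2, which encodes N-cadherin, by 0.23 (limma adjusted p = 0.739, 3 of 4 pairs). VIM ranged from 0.35 to 0.68 and CDH2 from 0.04 to 0.38 with 1 library left out. The 2 members with the lowest p were ITGB3, an integrin subunit, at 8.12 ± 7.66 and 22.4 ± 11.9 FPKM, and TNC, the matrix protein tenascin C, at 65.5 ± 33.1 and 127 ± 41.9 FPKM (SD, n = 4), both higher in 4 of 4 pairs. ITGB3 passed over the list alone in the blocked fit (adjusted p = 0.0426).

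**Figure D3:**
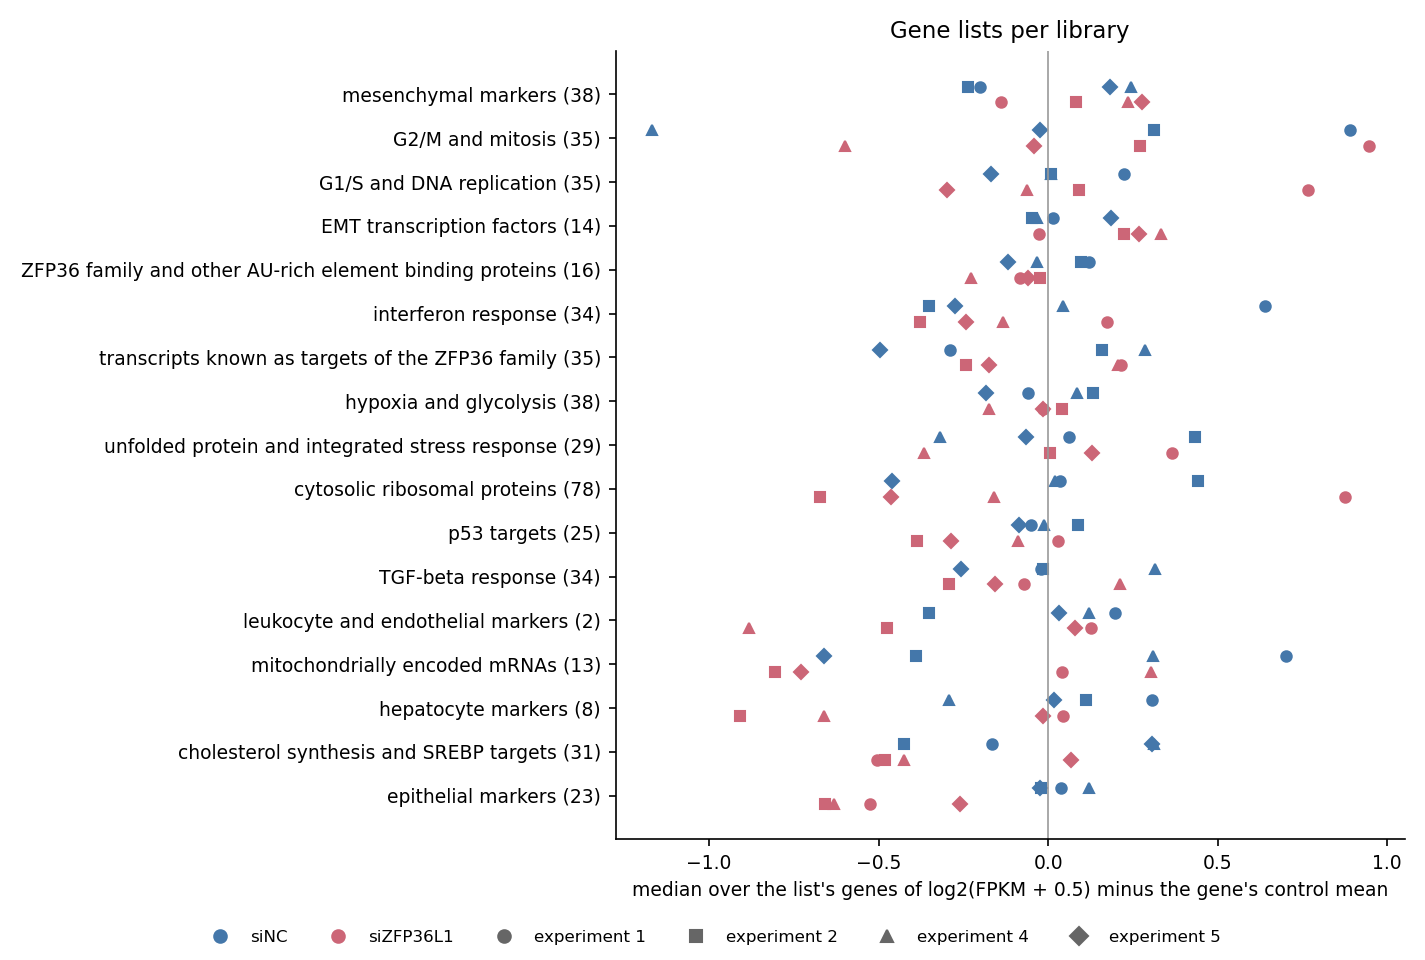
Median over each gene list, with the number of genes in brackets, of log2(FPKM + 0.5) minus the gene's control mean (horizontal axis), for each siNC (blue) and siZFP36L1 (red) library, with 1 marker shape per experiment number. The epithelial medians are -0.26 to -0.66 in the knockdown libraries and -0.02 to 0.12 in the controls.

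Transcripts known as targets of the ZFP36 family did not move as a group. The 35 measured members divided into 17 higher and 18 lower, with a median of -0.03 and a mean of -0.05, while camera gave a small upward statistic (adjusted p = 0.834). CCND3, which encodes the G1 regulator cyclin D3, averaged 15.6 ± 3.98 FPKM in siNC and 50.4 ± 15.3 FPKM in siZFP36L1 (SD, n = 4). Its log2 difference was 1.65 (SE 0.25, limma adjusted p = 0.0712), and it was the only member to pass adjusted over the list alone (adjusted p = 0.00285). Over all genes CCND3 passed with quantile normalization (adjusted p = 0.0178) and with limma voom (0.0389), and over its alternatives the adjusted p ran from 0.0178 to 0.392. Among the ZFP36 family and other AU-rich element binding proteins, 17 were measured, and 1 was higher and 2 lower adjusted over the list alone. Beside ZFP36L1 these were CNOT7, a deadenylase subunit, at a difference of 0.78, and ZC3H12A, an mRNA endonuclease, at -0.98 (adjusted p = 0.0387 for both over the list alone); with the block ZC3H12A had 0.0817. The paralogs ZFP36 and ZFP36L2 differed by -0.86 (limma adjusted p = 0.650, 3 of 4 pairs) and 0.34 (limma adjusted p = 0.586, 4 of 4 pairs). With 1 library left out, ZFP36 ranged from -1.44 (without control 5) to -0.40 (without control 2). That list's median was 0.06, its mean -0.09 and its test downward (camera adjusted p = 0.834).

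Cholesterol synthesis genes and other SREBP targets fell as a group by camera, with 24 of 31 members lower and a median of -0.39 (adjusted p = 0.00566; 0.00197 with the block). The call was lost with an estimated correlation (adjusted p = 0.924, blocked 0.624) and without control 4, control 5 or knockdown 1 (medians -0.30, -0.30 and -0.39), and fry gave an adjusted p of 0.741, or 0.437 with the block. TM7SF2, a sterol reductase, averaged 9.99 ± 2.87 and 3.23 ± 0.53 FPKM (SD, n = 4), and it alone passed adjusted over the list alone (adjusted p = 0.00174; limma adjusted p = 0.0638 over all genes). STARD4, a sterol carrier, differed by -0.69 (limma adjusted p = 0.410). The control medians of this list themselves ran from -0.43 to 0.31, and those of the knockdown libraries from -0.51 to 0.07.

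None of the other 11 lists passed by camera, and no member of them passed over all genes. In the TGF-beta list (median -0.16, camera adjusted p = 0.315), BAMBI, a decoy receptor of the pathway, differed by -1.24 and passed adjusted over the list alone (adjusted p = 0.0442). With the block PMEPA1 also passed lower and SMURF2 higher, while SMAD6 differed by -0.83. Of the unfolded protein and integrated stress response genes (median -0.09, mean -0.00478, test upward, camera adjusted p = 0.834), none passed adjusted over the list alone. In the blocked fit 3 did, all higher: PDIA4 and DNAJC3, chaperones of the endoplasmic reticulum, with differences of 1.12 and 0.91, and SLC7A11, a cystine transporter. Hepatocyte markers had 8 measured members, 6 of them lower (median -0.34, camera adjusted p = 0.225), and the median ranged from -0.90 with voom to 0.0591 without knockdown libraries 2 and 4. VTN and APOE, secreted by hepatocytes, differed by -1.25 and -1.59 and passed over the list alone only with the block (adjusted p = 0.0249 for both). VTN ranged from -1.62 to -0.91 and APOE from -2.03 to -0.95 with 1 library left out.

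In the other lists no member passed adjusted over the list alone, with or without the block. The p53 targets had a median of -0.11 (camera adjusted p = 0.225), with TP53INP1 at -1.37 and PHLDA3 at -0.69. The interferon response had a median of -0.02, or 0.0118 after quantile normalization (camera adjusted p = 0.225), with IFIT1 at -0.90 and BST2 at -1.59. Hypoxia and glycolysis genes had a median of -0.06 (camera adjusted p = 0.834), with PGAM1 at -0.72 and HK1 at 0.60. G1/S and DNA replication genes had a median of 0.13 and G2/M and mitosis genes of 0.16 (camera adjusted p = 0.315 for both), with GINS3 at 0.82, CCNE1 at -0.61, MKI67 at 0.81 and CDC25B at 0.37. MKI67 ranged from 0.44 to 1.14 and CDC25B from 0.16 to 0.47 with 1 library left out. The G2/M medians followed the experiment: -1.17 in control 4 and -0.60 in knockdown 4, against 0.89 and 0.95 in experiment 1. Mitochondrially encoded mRNAs had a median of -0.34 (camera adjusted p = 0.225), with MT-CYB at -1.90 and MT-ND6 at -1.73. Both values rest on knockdown library 2, where MT-CYB stood at 25 FPKM and MT-ND6 at 18.4 FPKM, and were -0.26 and -0.02 without it. All mitochondrial genes together, ribosomal RNAs included, took 3.48% to 11.9% of reads. Cytosolic ribosomal protein genes had a median of -0.10 (camera adjusted p = 0.315), with RPL22 at -0.56 and RPL23A at -0.88. RPL22 ranged from -0.81 to -0.37 and RPL23A from -1.39 to -0.46 with 1 library left out. Of the leukocyte and endothelial markers, 2 were measured, CD14 and TEK, at -0.79 and 0.22 (camera adjusted p = 0.834).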

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

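In this part, the comparison of genes with 1 and 3 reads and the reading of knockdown libraries 2 and 4 at equal depth as separate cases were chosen after the result was seen. Among 112 sets of 4 values (named genes' FPKM and library measures, per group), 7 held a value far from the other 3; chance gives about 1 in 20, or 5.6. CDC25B stood at 37.3 FPKM in control library 4 against 65.6 to 70.1 in the other controls. In knockdown library 4, ITGB3 stood at 40.0 FPKM against 14.9 to 18.7, TNC at 189 FPKM against 96.9 to 112, and TEK at 0.868 FPKM against 1.39 to 1.45 in the other knockdown libraries. TM7SF2 stood at 2.44 FPKM in knockdown library 2 against 3.46 to 3.53. SNAI1 stood at 13.4 FPKM in knockdown library 1 against 4.91 to 5.48. FP671120.1 stood at 0.447 FPKM in knockdown library 5 against 0 in the other knockdown libraries.

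Knockdown libraries 2 and 4 held fewer genes above 0 than most others. With all libraries thinned to 12.9 M reads, library 2 had 19897 genes, 2253 below the lowest control (22150), so fewer reads alone do not account for it. Library 4 had 22360, within the control range, so against the controls as a group fewer reads stay open as the cause. At equal depth it still lay below control 4 (25494), so fewer reads alone do not account for that gap. Knockdown libraries 1 and 5 had 22439 and 25509 genes at equal depth, within the controls' 22150 to 25897. Loss of ZFP36L1 therefore did not put every knockdown library below the controls. Against the control of the same number, libraries 2, 4 and 5 were lower (controls 24368, 25494 and 25897) and library 1 higher (22150). A part of the knockdown in the lower counts stays open. Genes with 1 read were 1.05 and 1.12 times as many as genes with 3 reads in knockdown libraries 2 and 4. In the other 6 they were at least 2.05 times as many, a difference that few starting molecules, each sequenced several times, could give. Neither RNA input nor duplicate rate was analysed here, so this stays a hypothesis.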

How the results depend on the processing

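In this part, the results with limma voom, without knockdown libraries 2 and 4, with the block and arrayWeights, and with the block and fry were chosen after the data were seen. Of 47 named genes besides ZFP36L1 and ZEB2, 45 had 1 sign under every alternative run (19, but 18 for VTN, which a mean FPKM of at least 1 left out); TWIST1 and RPL23A did not. ZEB2 stayed higher in all 19 (0.61 to 1.06), with an adjusted p above the threshold in each (0.103 to 0.978). At this depth CLDN3 rested on 8 to 89 reads per library.

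The 7 calls (2 higher, 5 lower) became 4 (1 higher, 3 lower) with no filter, where more genes were tested, and 4 (1 and 3) with eBayes without trend. arrayWeights gave 11 (4 higher) and limma voom 12 (6 higher). The replicate block gave 0 (0 and 0; limma, 2374 at an unadjusted p under 0.05), with all 7 genes under an adjusted p of 0.1, and the block with arrayWeights 850 (420 and 430), a fit in which the 2 libraries of experiment 5 carry most weight (4.75 each). Without knockdown libraries 2 and 4 limma called 0 (0 and 0; 758 at an unadjusted p under 0.05), with fewer samples. Leaving out 1 library gave 2 to 20 calls (0 to 8 higher, 2 to 12 lower): 2 without control 1 or 5, 4 without control 2, 3 without control 4 or knockdown 4, 5 without knockdown 2 or 5, and 20 without knockdown 1. ZFP36L1 kept its difference of -3.02 with the block (adjusted p = 0.0531) and had -2.87 without knockdown libraries 2 and 4 (adjusted p = 0.172), both above the threshold of 0.05; over its alternatives the adjusted p was 0.00182 to 0.172.

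Medians of gene lists near 0 changed sign. The ZFP36 targets had 0.00609 with a pseudocount of 0.1, 0.0660 with arrayWeights, 0.00899 with voom and -0.17 to 0.13 with 1 library left out. The interferon list had 0.0118 with quantile normalization, 0.0039 with voom and -0.18 to 0.10 with 1 library left out. With arrayWeights, G1/S genes had -0.000127, G2/M genes -0.0495, cholesterol genes -0.28 (call lost) and ribosomal protein genes -0.24 (call gained). Epithelial markers at -0.48 and cholesterol genes at -0.39 lost their calls with an estimated correlation and in fry with the block, and cholesterol genes also in fry without it. The estimated correlation was 0.431 for cholesterol genes but -0.00171 for epithelial markers, below the preset 0.01. Without knockdown libraries 2 and 4, camera with the preset correlation gained calls for G2/M (0.44), TGF-beta (-0.13), mitochondrial (-0.33) and ribosomal protein genes (0.20, sign changed). With all libraries and an estimated correlation each of these had a camera adjusted p of 0.924, but none was called there with the preset correlation either. No estimated correlation was run without knockdown libraries 2 and 4, so the 0.924 does not test these gained calls. The sign also changed there for the AU-rich binding proteins (-0.0629), hypoxia (0.0252), hepatocyte (0.0591), stress response (0.25), p53 (0.03997) and leukocyte and endothelial lists (0.10), and for RPL23A (0.17).

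With 1 library left out, the ranges were -0.0137 to 0.32 for mesenchymal markers, -0.30 to 0.45 for G2/M, -0.12 to 0.27 for G1/S, -0.10 to 0.0336 for hypoxia, -0.27 to 0.19 for the stress response, -0.54 to -0.0852 for mitochondrial mRNAs, -0.44 to 0.10 for ribosomal proteins and -0.0639 to 0.11 for AU-rich binding proteins. They were 0.04 to 0.21 for EMT transcription factors, -0.63 to -0.12 for hepatocyte markers, -0.19 to -0.01 for TGF-beta, -0.23 to -0.05 for p53 targets and -0.43 to -0.09 for leukocyte and endothelial markers. Hepatocyte markers also had -0.65 and -0.20 with pseudocounts of 0.1 and 1, -0.0621 with no filter and -0.90 with voom. By camera with the preset correlation, calls were gained for ribosomal proteins without knockdown 1 (adjusted p = 2.18e-08) or control 5 (0.00463), for G2/M without control 1 (0.00101) or knockdown 4 (0.00496), for G1/S without knockdown 5 (0.0102), for interferon without control 2 (0.00763), and for mitochondrial mRNAs without control 2 (0.0378), control 5 (0.0108) or knockdown 4 (0.0113). With all libraries none of these lists was called with the preset correlation, and each had a camera adjusted p of 0.924 with an estimated one. The 0.924 does not test the calls with 1 library left out, for which no estimated correlation was run. Over all alternatives the adjusted p, by camera or fry, ran from 0.000481 to 0.213 for epithelial markers and from 1.78e-06 to 0.924 for cholesterol genes. With 1 library left out, epithelial markers ranged from -0.59 to -0.39, with the call lost without knockdown library 1 (-0.59), and their median was -0.16 with no filter. Cholesterol genes ranged from -0.47 to -0.30, with the call lost without control 4 (-0.30), control 5 (-0.30) or knockdown 1 (-0.39), and their median was -0.13 without knockdown libraries 2 and 4. TWIST1 had -0.000801 after rescaling, -0.0179 after quantile normalization, -0.0305 with arrayWeights and -0.40 to 0.35 with 1 library left out. Where no cause is named, the cause was not tested. The block changed no call other than those given.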

Other observations

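In this part, the sites in named genes and lists, the differences per pair and the counts of splits for gene lists and heptamers were chosen after the results were seen. Genes with the heptamer ACAUCUU in the 3' UTR were lower after ZFP36L1 siRNA once 3' UTR length, GC content and mean FPKM were adjusted for. Of 16193 heptamers, 11 went with lower and 10 with higher log2 differences at a Benjamini-Hochberg p under 0.05 across genes, which are not independent replicates. The lowest was ACAUCUU, in 1746 genes, with an adjusted difference of -0.140; next came CAUCUUA, the same sequence shifted by 1 base, at -0.12. The ACAUCUU difference was -0.14, -0.13, -0.16 and -0.13 in experiments 1, 2, 4 and 5, the libraries in which it was picked. ACAUCUU was present in 25.4% of 674 genes lower at an unadjusted p under 0.05, 13.5% of 668 higher genes and 15% of all, and TRIM26, RAB14 and PUDP carry it. MET, which rose, carries it too, as do ZEB2, CNOT7 and MKI67, which had higher means after the knockdown. Without adjustment the median log2 differences of carriers and of other genes were 0.01 and -0.01.

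A shared heptamer of this kind may reflect matches to the seed of an siRNA guide, the prediction tested with the value of -0.140. That prediction asked only that some heptamer go with lower differences at a Benjamini-Hochberg p under 0.05 and beyond a fixed size. The lowest t of the other splits ran from -11.6 to -4.01. Such splits can hold part of the real contrast: where the lowest t was -11.6, ACAUCUU itself still differed by -0.0751. They therefore do not show what t would arise without a seed effect, and a strongly negative t alone does not settle one. ACAUCUU differed by at most 0.078 in size in any other split, but it was picked in the real one. In annotated ZFP36L1 transcripts ACAUCUU occurs once, in the 3' UTR (chromosome 14, 68788646 to 68788652, minus strand). The siRNA sequences were not analysed here, so whether a guide was directed to that place stays open. The t of -12.9 was not reached in size by any heptamer in the other splits of the libraries (highest 11.6). Only 1 of 35 splits, the real one, was as large, which is the smallest share possible. This argues against chance only over splits that ignore the pairing and does not exclude it. The split with 11.6 also parts all 4 pairs, and the 8 splits that do so are too few for a share under 0.05. Among epithelial markers, the 4 with ACAUCUU or CAUCUUA had a median log2 difference of -0.15 and those without it -0.61, so these sites do not account for the lower median of that list. In the other direction, carriers of GACGUAA (140 genes) differed by 0.24, with 0.25, 0.17, 0.26 and 0.28 in the 4 experiments. The 3' UTR of MET, which rose, holds 1 copy of GACGUAA. What this heptamer reflects was not tested.

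Transcripts with the AU-rich heptamer UAUUUAU, the core of the ZFP36 family's binding site, were on average higher after ZFP36L1 siRNA. Carriers (4104 genes) exceeded genes without it by 0.0775 log2 units at matched 3' UTR length and mean FPKM (permutation p = 0.0001 across genes, the smallest that 10000 permutations give). Without matching, it was present in 49.9% of the higher and 26.6% of the lower genes at an unadjusted p under 0.05, against 35.4% of all genes. The unmatched means were 0.074 in carriers and -0.086 in other genes, further apart than at matched 3' UTR length and mean FPKM. ZEB2 carries 7 copies and MET 2, but SRPRA, which rose, and CCND3 carry 0, and the carriers ZFP36, STARD4 and TP53INP1 had lower means after the knockdown. Among known targets of the ZFP36 family, the 29 carriers had a median of -0.03 and the others 0.03. The 0.0775 could come from loss of ZFP36L1-directed decay, but the known targets with UAUUUAU were not higher. Experiment 1 gave -0.01 against 0.17, 0.09 and 0.06 in experiments 2, 4 and 5. Knockdown libraries 2 and 4 are those with few genes of 1 read. Of the 35 splits, 4, the real one among them, gave a difference as large in size, up to 0.0916. The others keep knockdown libraries 2, 4 and 5 together and so hold part of the real contrast. Their values therefore neither exclude chance nor show it. AU content in general stays open too: the 95th percentile of the 20 other heptamers of the same composition was 0.0759, and their highest 0.0775. With GC content held as well, UAUUUAU ranked 1 among them at 0.04.

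The number of changed genes was not matched by any other split of the 8 libraries: 1 of 35, the real one, gave 7 calls, and the highest other gave 5. That other split parts experiments 1 and 2 from 4 and 5. A share of 1 in 35 is the smallest possible here, and these splits ignore the pairing. It argues against chance only where the pairing is ignored and does not exclude it. The 8 splits that part all 4 pairs are too few for a share under 0.05; the real one gave 7 and the highest other 0. With the block limma called 0 genes, with 2374 at an unadjusted p under 0.05 (voom without the block called 12). By unadjusted p under 0.05, however, 3 other splits exceeded the real 1556, up to 2918 where knockdown library 1 changed places with a control, a structure of the samples beyond the groups. For the number of gene lists called, chance could not be excluded, since 33 of 35 splits called at least the real 2 lists. The highest other called 9. Which lists other splits called was not examined.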
